A study of Mus musculus with 8 samples.

How the data were processed

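Polysomal mRNA was isolated from batches of 160 to 500 mouse eggs or embryos per array, per the labels, with 4 independent replicates of metaphase II oocytes and 4 of one-cell embryos treated with α-amanitin. Per the labels, the RNA went through 2 rounds of amplification by in vitro transcription and was labelled with biotin, so each array carries 1 colour. The authors deposited 1 linear intensity per probe set and array. The array software, the scaling method and any genome build are not given in the sources used here. From the values, the mean intensity after leaving out the lowest and highest 2% of probe sets was 150.0 on each of the 8 arrays, so the deposited intensities had been scaled to a common mean. The column medians (26.9 to 71.8) differed, so no quantile or similar normalization had been applied. The intensities are in arbitrary units, and the table used here has no detection calls. Amplification in 2 rounds favours the 3′ ends of mRNAs, and scaling to a common mean removes any change in the total amount of polysomal mRNA.

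The table holds 45101 probe sets, of which 64 are controls that were used to describe the arrays and were left out of the tests. GEO's platform annotation gave exactly 1 gene symbol to 34945 of the other probe sets, several to 932 and none to 9160. Probe sets with several genes or none entered the tests but were not named. Of 12359 symbols measured, 12335 are in the RefSeq gene table, which was used for names. Coordinates are not given, since the files state no genome build.

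The main setting followed rules set before the data were examined, as did the tests, the 20 gene lists and the rule for naming genes. Intensities were used as deposited because the trimmed means agreed within 5%. An offset of 10, the 25th percentile of the table, was added before log2. A probe set was kept if it lay above the array's own median on at least 4 of the 8 arrays, which kept 23336 (20009 with 1 gene, 535 with several and 2792 unnamed). The contrast of one-cell embryo minus MII oocyte was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, Benjamini-Hochberg over the probe sets kept, threshold 0.05). A gene was represented by its brightest kept probe set. Gene lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg over the lists, then with an estimated correlation and with fry. None of the 3 lists that passed did so with an estimated correlation. Array measures were compared by two-sided exact permutation tests. The lists were drawn up from general knowledge of the genes and not from these samples.

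Genes were named by 3 rules. The first took the 12 largest changes in each direction among genes past the test whose groups did not overlap and whose mean in the brighter group exceeded 109, the mean of the arrays' 75th percentiles, leaving out clone and prediction names. This left 2027 higher and 1550 lower genes to choose from. The second took the 3 members of each list with the smallest p, and the third a panel of 16 genes, of which 14 were measured (Ccnb1 and Npm2 were not analysed here, since no probe set used is named for them). The 92 genes named this way include 87 past the test. Bub1b, Wee1, Rps2, Pcna, Hspa1b, Usp17la, Dnmt3a, Col4a1 and Nr5a2, and the genes named under other observations, were chosen after their values were seen.

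The procedure was tested on simulated data: over 5 runs with 200 of 23336 probe sets changed and the spread of the real arrays pooled over both groups, 1.2% of 2-fold and 37.4% of 4-fold changes passed the test for the one-cell embryo and MII oocyte comparison, and 2.51% of calls were false. In the real comparison 7493 probe sets passed, which makes the Benjamini-Hochberg threshold less strict, so these rates do not carry over to it. The simulated groups also had equal spread, while the real one-cell arrays agreed less with each other than the MII arrays did. False calls under unequal spread were therefore not tested. Small changes can still be missed at this number of arrays. A shifted ribosomal protein list was called in 20 of 20 simulated runs of 12359 genes, with 0 false list calls. Genes varied independently in these runs, so they do not test for false list calls among correlated genes. Estimated correlations in the real arrays were 0.14 (ribosomal proteins), 0.108 (oxidative phosphorylation) and 0.253 (mRNAs recruited during maturation). Alternatives covered the normalization between arrays (quantile, median centring), the offset, the filter on dim probe sets, the variance model, array quality weights, the replicate number as a block, each array left out in turn, the mean over a gene's probe sets, stricter thresholds and the estimated inter-gene correlation. After the uneven hybridization controls had been seen, these were added: the control signal as a covariate, the comparison without one-cell arrays 1 and 4, and 2 settings without one-cell array 1 that also change the normalization or the correlation.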

Results

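Messenger RNA bound to polysomes, the clusters of ribosomes that carry mRNAs under translation, was measured in mouse eggs before fertilization and in embryos before the first cleavage. The 8 arrays held 4 batches of oocytes arrested at metaphase II (MII) and 4 batches of one-cell embryos that had been treated with α-amanitin, an inhibitor of RNA polymerase II that blocks new transcription. The comparison addresses which maternal mRNAs enter or leave polysomes between the egg and the one-cell embryo. Embryo stage and α-amanitin treatment changed together, so no value here separates them. Signals are relative to the total of each array, and total mRNA was not analysed here, so they do not separate the abundance of an mRNA from its loading onto ribosomes. The number of arrays, 4 per group, limits the precision.

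The arrays were not equal in quality. Correlations of log2 signal between MII arrays lay between 0.933 and 0.952, those between one-cell arrays between 0.810 and 0.945, and those between the groups between 0.719 and 0.885. One-cell array 1 stood apart, with a median signal of 71.8 against 26.9 to 37.9 on the other arrays. Its 18 hybridization controls, which are added in fixed amounts, had a geometric mean of 14879 against 857 to 3718 on the other one-cell arrays and 905 to 1364 on the MII arrays. The group difference of these controls (3.04-fold) gave p = 0.143 in a two-sided exact permutation test. The probe set at the 3′ end of 18S ribosomal RNA was 11.3-fold brighter on the one-cell arrays and higher on all 4 of them (exact p = 0.0286, the smallest that 4 against 4 arrays allow, and 0.293 after Benjamini-Hochberg adjustment over 12 array measures). The middle and 5′ probe sets of 18S were 2.345-fold and 1.555-fold brighter, with overlapping groups (exact p = 0.114 and 0.0857). The ratios of 3′ to 5′ signal, a measure of RNA integrity, gave exact p = 0.914 for Actb and 0.171 for Gapdh. The Actb ratio was 65.9 on MII array 2 against 4.49 to 11.6 on the other 7 arrays.

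**Figure D1:**
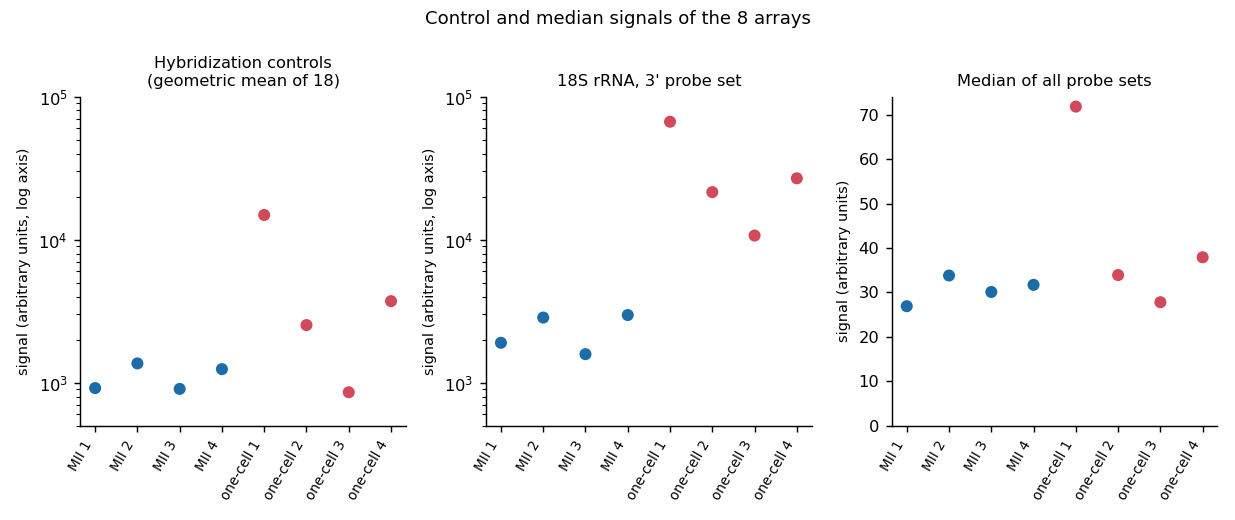
Signals in arbitrary units on each of the 4 MII oocyte arrays (blue) and the 4 one-cell embryo arrays (red): the geometric mean of 18 hybridization controls and the 3′ probe set of 18S ribosomal RNA on log axes, and the median of all probe sets on a linear axis. One-cell array 1 has the highest value in each panel, and the 18S 3′ signal is higher on all 4 one-cell arrays (10688 to 66754) than on any MII array (1583 to 2971).

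Polysomal mRNA of Mos, the kinase that holds the egg at metaphase II, was 47.4-fold lower in one-cell embryos. Its signal was 14610 ± 3168 (SD, n = 4) in MII oocytes and 301 ± 90.6 in one-cell embryos, a log2 change of -5.57 ± 0.31 (SE, adjusted p = 1.52e-08). Plat, the tissue plasminogen activator whose stored mRNA is taken into translation during maturation, changed by -3.30 ± 0.33. That is the value of its brightest probe set: the only other one kept did not pass the test (0.93 ± 0.40), and the mean of both changed by -1.19 ± 0.24 (adjusted p = 0.00166). The oocyte growth factor Gdf9 changed by -2.17 ± 0.43, and the oocyte linker histone H1f8 by -1.999 ± 0.35. In the other direction, mRNAs of the ribosomal protein Rpl7a (3.42 ± 0.27) and of the elongation factor Eef2 (2.92 ± 0.27) rose, as did Izumo1r, the egg's receptor for sperm (4.00 ± 0.32). All log2 changes are one-cell embryo minus MII oocyte on log2(signal + 10) with the limma SE, and they understate the change of dim mRNAs.

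Of 23336 probe sets kept, 7493 differed between the groups at an adjusted p under 0.05, with 4511 higher and 2982 lower in one-cell embryos. Counted over 12359 genes, 2480 were higher and 1815 lower. At least 4-fold changes were found in 877 genes that rose and 326 that fell. The groups did not overlap in 7612 probe sets (32.6% of those kept, where chance gives 2.86%). The share of changed probe sets that were higher rested on the scaling and on the filter for dim probe sets. It was 60.2% with the signals as deposited, 48.6% after quantile normalization, 50.8% with each array centred on its median and 52.4% with only probe sets above the 75th percentile. The median change of all kept probe sets was 0.17 as deposited, -0.12 after quantile normalization and -0.15 after centring. It was 0.03 without one-cell array 1 and 0.27 without one-cell array 3, so gene lists are given relative to the median of all genes.

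The largest falls were those of Tbc1d14 (-6.00 ± 0.28), Mos and Lbr, the lamin B receptor of the inner nuclear membrane (-5.15 ± 0.27). Lbr signal was 4987 ± 571 (SD, n = 4) in oocytes and 132 ± 26.2 in embryos. Slc35b3, a nucleotide-sulfate transporter of the Golgi, changed by -4.72 ± 0.35, Slmap by -4.59 ± 0.32, the interleukin receptor subunit Il1rap by -4.55 ± 0.35 and the ubiquitin ligase Marchf7 by -4.51 ± 0.34. The glycosyltransferase Galnt9 (-4.24 ± 0.37), the heparan sulfate epimerase Glce (-4.23 ± 0.29), the cargo receptor Tmed9 (-4.21 ± 0.31), the peroxidase Pxdn (-3.98 ± 0.26) and the checkpoint clamp subunit Hus1 (-3.98 ± 0.33) complete the 12 largest falls. Another probe set of Tbc1d14 rose (1.99 ± 0.32), and so did another of Hus1 (1.70 ± 0.41), while the remaining probe set of Tbc1d14 fell (-3.49 ± 0.40). Averaged over their probe sets, both genes still fell, by smaller amounts (-2.50 and -1.14). The falls of Il1rap, Glce and Slmap rest mainly on 1 probe set. None of the other kept probe sets of Il1rap (2) and Glce (1) passed the test, nor did 1 of the 2 others of Slmap, and averaged over its probe sets the change was -1.37 for Il1rap, -1.57 for Glce and -1.97 for Slmap. Galnt9 lay at or under the array median on all 4 one-cell arrays (5.8 ± 4.9, SD, n = 4), so its fold and its place among the 12 are poorly set.

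The largest rises were those of Cd7, a surface protein known from lymphocytes (5.27 ± 0.41), the SNARE protein Stx5a (5.04 ± 0.38), the selenocysteine elongation factor Eefsec (4.91 ± 0.41), the apoptosis inhibitor Aven (4.90 ± 0.39) and Faf1 (4.90 ± 0.40). They were followed by the growth factor Fgf8 (4.72 ± 0.37), the actin-binding peptide Tmsb10 (4.71 ± 0.50), the mitochondrial ribosome protein Mrpl58 (4.71 ± 0.34), the mitochondrial initiation factor Mtif3 (4.68 ± 0.34) and the RNA polymerase III subunit Polr3a (4.65 ± 0.31). Lrrfip2 (4.60 ± 0.27) and Cpsf4l (4.55 ± 0.28) complete the 12. Stx5a rose from 330.8 ± 142.6 to 11210 ± 5066 (SD, n = 4) and Cpsf4l from 135 ± 29.4 to 3376 ± 676. Of the 12, Cd7, Eefsec, Fgf8, Mrpl58 and Mtif3 lay at or under the array median on all 4 MII arrays, so their oocyte level and hence their fold is poorly set. The mean MII signal of Faf1 (20.5 ± 17.2, SD, n = 4) also lay below the median of each MII array (26.9 to 33.8), so its fold is poorly set too. The other kept probe set of Faf1 and that of Mrpl58 did not pass the test, and with both probe sets averaged the changes were 2.78 and 2.59.

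Among 16 maternal, cell cycle and early embryo genes named in advance, 14 were measured. Besides Mos, Plat, Gdf9 and H1f8, the maternal-effect gene Zar1 (-1.005 ± 0.35, adjusted p = 0.0385) and the maintenance DNA methyltransferase Dnmt1 (-1.05 ± 0.33, adjusted p = 0.02) fell. Nlrp5, a part of the subcortical maternal complex (1.09 ± 0.30), the pluripotency factor Pou5f1 (1.17 ± 0.28) and the replication licensing factor Cdc6 (1.07 ± 0.34) rose. The abundant maternal mRNAs Btg4 (0.17 ± 0.47), Spin1 (0.15 ± 0.45), Dppa3 (-0.14 ± 0.41) and Zp3 (0.15 ± 0.31) did not pass the test, nor did Ccne2 (-0.38 ± 0.34). Btg4 signal, for example, was 23830 ± 4228 (SD, n = 4) in oocytes and 28590 ± 12030 in embryos. The calls of Zar1, Dnmt1 and Cdc6 were lost after quantile normalization, where their changes were smaller (-0.53 ± 0.22, -0.58 ± 0.27 and 0.65 ± 0.31, adjusted p = 0.0925, 0.123 and 0.138). They were also lost after centring, with larger changes for Zar1 (-1.32 ± 0.50) and Dnmt1 (-1.37 ± 0.49) and a smaller one for Cdc6 (0.76 ± 0.32; adjusted p = 0.0691, 0.057 and 0.104), and that of Dnmt1 with its probe sets averaged (-0.80 ± 0.30, adjusted p = 0.0512). Nlrp5 (0.77 ± 0.48) and Pou5f1 (0.86 ± 0.42) lost theirs after centring (adjusted p = 0.265 and 0.152). With 7 arrays Zar1 missed the threshold without any 1 of the MII arrays or without one-cell array 3 or 4 (adjusted p from 0.0534 to 0.108), as did Dnmt1 without MII array 3 (0.0786) or one-cell array 4 (0.0646), and Cdc6 without MII array 1 (0.0833) or 3 (0.0616) or one-cell array 3 (0.0662). The changes stayed near their values with all arrays, from -1.07 to -0.93 for Zar1, -0.98 and -0.92 for Dnmt1 and 0.92 to 1.04 for Cdc6, with wider SEs (0.39 to 0.42, 0.37 and 0.37 to 0.39).

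**Figure D2:**
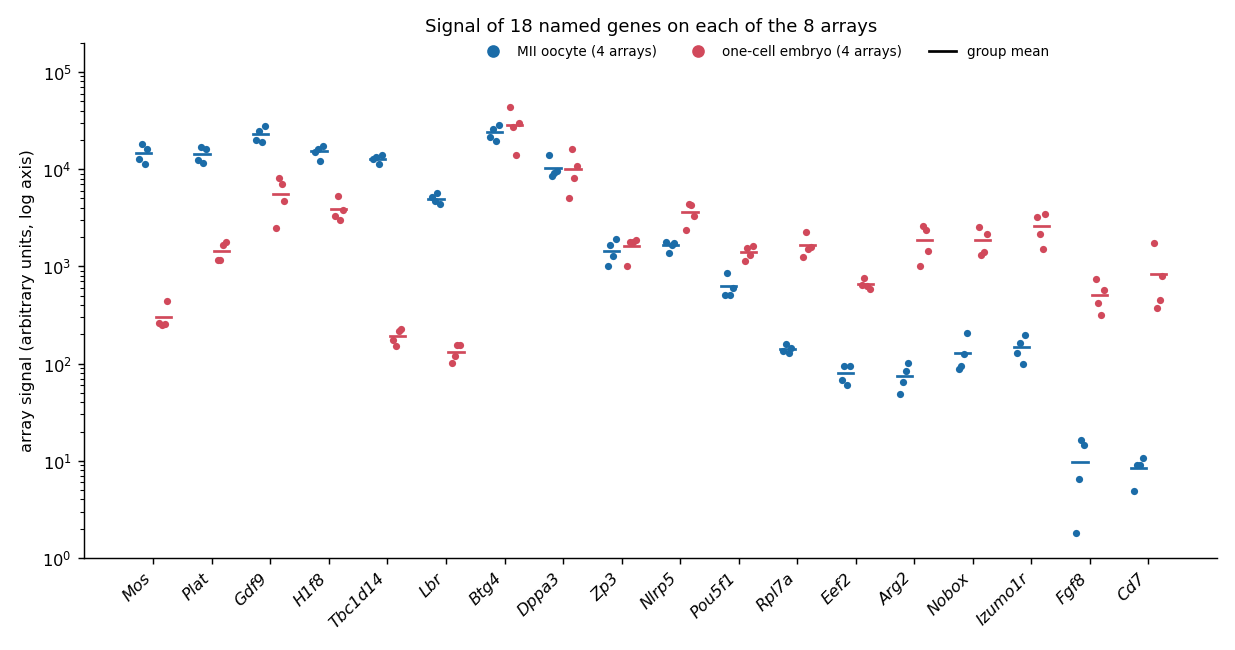
Array signal in arbitrary units (log axis) of 18 named genes, with a point for each of the 4 MII oocyte arrays (blue) and the 4 one-cell embryo arrays (red) and a line at each group mean. Mos falls from a mean of 14610 to 301, Btg4, Dppa3 and Zp3 overlap between the groups, and Izumo1r rises from 147.5 to 2573.

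Genes whose mRNAs are known to be recruited to polysomes during oocyte maturation fell as a group. Of 31 measured members, 15 were lower and 3 higher in one-cell embryos (16 and 3 adjusted over the list alone), and the list median lay at -1.13 relative to all genes (limma camera, adjusted p = 3.25e-05 over 20 lists, and adjusted p = 0.578 with an estimated correlation). The relative median was smaller in some settings: -0.71 without one-cell array 1 (adjusted p = 0.000122, and adjusted p = 0.452 with an estimated correlation), -0.52 with the hybridization controls as a covariate (adjusted p = 0.00208) and -0.35 after quantile normalization without that array (adjusted p = 0.00208). Mos and Plat led the list, and the spindle checkpoint kinase Bub1b (-2.08 ± 0.47) and the decapping enzyme Dcp2 (-1.66 ± 0.28) were among those that fell, although another probe set of Dcp2 rose (2.92 ± 0.31). Averaged over both probe sets, Dcp2 rose by 0.63 ± 0.23 (limma, adjusted p = 0.0475), so its direction is not settled. The kinase Wee1 (1.89 ± 0.41) rose. In the list for meiosis, the spindle and metaphase II arrest, 26 of 83 members fell and 21 rose (32 and 21 adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.134). Beside Mos, its leading members were the spindle protein Tacc3 (3.98 ± 0.33) and the anaphase-promoting complex subunit Anapc7 (2.99 ± 0.28, and 1.05 ± 0.27 as the mean with its other probe set, which did not pass).

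Cytoplasmic ribosomal protein genes rose together. Of 37 measured members, 20 were higher and 1, Rps2 (-2.01 ± 0.29), was lower (21 and 3 adjusted over the list alone), with a median of 1.04 relative to all genes (camera adjusted p = 0.00186, and adjusted p = 0.578 with an estimated correlation). Rpl7a rose from 141 ± 13.2 to 1649 ± 437 (SD, n = 4), Rps7 by 3.06 ± 0.28 on the log2 scale and Rps4x by 3.10 ± 0.30. Nuclear genes of oxidative phosphorylation rose as well, with 31 of 69 members higher and 3 lower (33 and 5 adjusted over the list alone) and a relative median of 0.61 (camera adjusted p = 0.00186, and adjusted p = 0.578 with an estimated correlation). The ATP synthase subunits Atp5j2 (3.81 ± 0.32) and Atp5g1 (3.66 ± 0.39) and the complex I subunit Ndufb7 (3.01 ± 0.34) led it, the last 2 from signals at or under the median of each MII array. Averaged over its 3 probe sets, of which 1 did not pass, Atp5j2 changed by 2.50. Limma's fry, which asks whether a list's genes move one way without comparing them with other genes, gave adjusted p = 0.00146 for the ribosomal proteins, 0.00178 for oxidative phosphorylation and 0.00497 for the mRNAs recruited during maturation. It passed 8 of the 20 lists, so it does not set these apart. With fry, molecular chaperones and early embryonic genome activation gave adjusted p = 0.000524 each. Translation factors gave 0.0015, glycolysis and tricarboxylic acid cycle genes 0.00246 and proteasome subunits 0.0102. After quantile normalization the relative medians of the ribosomal, oxidative phosphorylation and maturation lists were 0.88, 0.71 and -0.67. The 18S 3′ signal was 11.3-fold higher on the one-cell arrays, against 2.345-fold and 1.555-fold for the middle and 5′ probe sets. The hybridization controls of one-cell array 1 were the brightest of the 8 arrays.

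Among translation factors, 23 of 56 members rose and 7 fell (24 and 11 adjusted over the list alone). Eif2b4 (4.23 ± 0.39, at or under the median of each MII array), Eef1d (3.11 ± 0.28) and Eef2 led the list, and Eef1d changed by 2.03 as the mean of its 3 probe sets, of which 1 did not pass. Of 44 glycolysis and tricarboxylic acid cycle genes, 16 rose and 7 fell (19 and 8 adjusted over the list alone), led by Aldoa (2.97 ± 0.32), Dlst (2.82 ± 0.33, and 1.57 as the mean with its other probe set, which did not pass) and Pkm (2.94 ± 0.38). Of 75 molecular chaperones, 27 rose and 6 fell (27 and 7 adjusted over the list alone), with Dnajc11 (3.86 ± 0.29), Bag4 (3.45 ± 0.29) and Hsph1 (2.96 ± 0.29) in front. Averaged over its 3 probe sets, of which 1 did not pass, Dnajc11 changed by 1.95. Of 12 genes known from early embryonic genome activation, 5 rose and 0 fell, with the same counts adjusted over the list alone: Arg2 (4.40 ± 0.34), Dppa2 (3.22 ± 0.32), Dppa4 (1.74 ± 0.37), Hspa1b (1.49 ± 0.36) and Usp17la (0.85 ± 0.32). These embryos had been treated with the transcription inhibitor. As lists, these 4 passed fry but not camera (camera adjusted p = 0.121, 0.121, 0.121 and 0.082). Without one-cell array 1, the array with the brightest controls, each of them passed as higher (adjusted p = 0.0369, 0.0329, 0.0442 and 0.0329), as they did after quantile normalization (0.0122, 0.0413, 0.0295 and 0.0413), which in either case brought the number of shifted lists from 3 to 7. With an estimated correlation none of the 4 passed: the adjusted p was 0.452 for each without that array, and 0.589, 0.578, 0.578 and 0.578 with all arrays. Of 39 proteasome subunits, 15 rose and 3 fell (15 and 4 adjusted over the list alone, camera adjusted p = 0.194), led by Psmc2 (3.57 ± 0.28), Psmd6 (3.37 ± 0.33) and Psma6 (3.13 ± 0.38, and 2.03 as the mean of its 3 probe sets, of which 1 did not pass).

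The lists for replication, repair, chromatin, transcription, splicing and mRNA decay each held rises and falls. Of 63 replication genes, 19 rose and 16 fell (19 and 18 adjusted over the list alone), with Orc2 (2.37 ± 0.26), Gins4 (2.79 ± 0.32) and Topbp1 (3.25 ± 0.41) leading and Pcna (-2.10 ± 0.49) among the falls. Of 60 DNA repair genes, 19 rose and 15 fell (20 and 17 adjusted over the list alone). The double-strand break repair genes Rad50 (2.05 ± 0.26), Mre11a (2.34 ± 0.30) and Xrcc6 (2.66 ± 0.34) rose, with 1.28 for Mre11a as the mean with its other probe set, which did not pass. Of 91 chromatin genes, 17 rose and 17 fell (17 and 21 adjusted over the list alone). The arginine methyltransferase Prmt1 (-2.46 ± 0.29) and the deacetylase Sirt1 (-2.29 ± 0.35) fell, and Dnmt3l (1.89 ± 0.31) rose. RNA polymerase II and general transcription factor genes held 17 rises and 23 falls among 79 (19 and 25 adjusted over the list alone), led by Gtf2a1l (-2.68 ± 0.29), Med17 (2.67 ± 0.32) and Med26 (2.12 ± 0.27). Splicing genes held 18 rises and 23 falls among 64 (19 and 25 adjusted over the list alone), led by Snw1 (2.78 ± 0.28), Sart1 (2.27 ± 0.29) and Prpf3 (2.11 ± 0.29). The other probe set of Snw1 and that of Sart1 did not pass, and with both averaged the changes were 1.32 and 1.33. Poly(A) tail and decay genes held 17 rises and 22 falls among 89 (19 and 24 adjusted over the list alone). There the antiproliferative gene Btg1 fell (-3.59 ± 0.34), and the RNA-binding proteins Ybx3 (3.60 ± 0.35) and Ybx2 (3.92 ± 0.39), which package stored mRNA in germ cells, rose. None of these 6 lists was shifted by limma camera (adjusted p from 0.168 to 0.801).

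Oocyte-specific and maternal-effect genes also split, with 14 of 62 higher and 9 lower (15 and 14 adjusted over the list alone, camera adjusted p = 0.801). Izumo1r and the oocyte transcription factor Nobox (3.77 ± 0.32) rose, and Astl, the cortical granule protease that cleaves the zona pellucida after fertilization, fell (-2.32 ± 0.30). In the list for fertilization, calcium signalling and cortical granules, 8 of 42 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.838). Izumo1r, Plat and the kinase Yes1 (-2.57 ± 0.30) led it. Of 28 apoptosis regulators, 7 rose and 6 fell, also with the same counts adjusted over the list alone (camera adjusted p = 0.628). The calcium-binding protein Pdcd6 (-2.54 ± 0.34) and the death activator Bcl2l11 (-2.21 ± 0.36) fell, and the survival gene Bcl2l1 (1.86 ± 0.31) rose. Of the other kept probe sets, 2 of 3 for Bcl2l11 and 1 of 2 for Yes1 did not pass, and averaged over all probe sets the changes were -1.19 for Bcl2l11 and -1.53 for Yes1.

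Few markers of other cells passed the test. Of 23 measured cumulus and granulosa markers, 2 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.838): Col4a2 (1.19 ± 0.35), Cyp11a1 (1.26 ± 0.42) and Gja1 (-1.54 ± 0.46). Each of these 3 calls was lost when some single array was left out: Col4a2 without MII array 3 (adjusted p = 0.0577) or one-cell array 4 (0.0671), Gja1 without MII array 1 (0.0766) or 2 (0.081), and Cyp11a1 without MII array 1, 2 or 3 or one-cell array 1 or 4 (0.0588 to 0.0844). In these settings the changes were 1.05 and 0.99 for Col4a2, -1.38 and -1.29 for Gja1 and 0.88 to 1.26 for Cyp11a1. Col4a2 also lost its call after quantile normalization (0.70, adjusted p = 0.213) and centring (0.87, 0.139), and Cyp11a1 with the hybridization controls as a covariate (0.49, 0.352). Of 17 sperm and spermatid markers, 1 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.838). The sperm protamine Prm2 rose from 30.3 ± 12.5 to 152 ± 69.3 (SD, n = 4), a log2 change of 1.96 ± 0.39 (adjusted p = 0.00103), and Hook1 (-2.01 ± 0.40) and Akap4 (-1.77 ± 0.41) fell. Hook1 signal was already 1778 ± 501 (SD, n = 4) in MII oocytes, before fertilization, so its fall does not report on sperm RNA. Gja1 (16.9 on average) and Akap4 (19.85) lay at or under the array median on all 4 one-cell arrays, so their folds are poorly set. In 6 lists the median, the mean and the camera test, which compares a list with all other genes, differed in sign. Replication genes had a median of -0.15, a mean of 0.16 and a test towards lower, and decay genes -0.05, 0.02 and lower. Medians and means were above 0 with a test towards lower for the oocyte-specific (0.02 and 0.07), DNA repair (0.0015 and 0.09), cumulus (0.12 and 0.08) and sperm (0.35 and 0.11) lists.

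**Figure D3:**
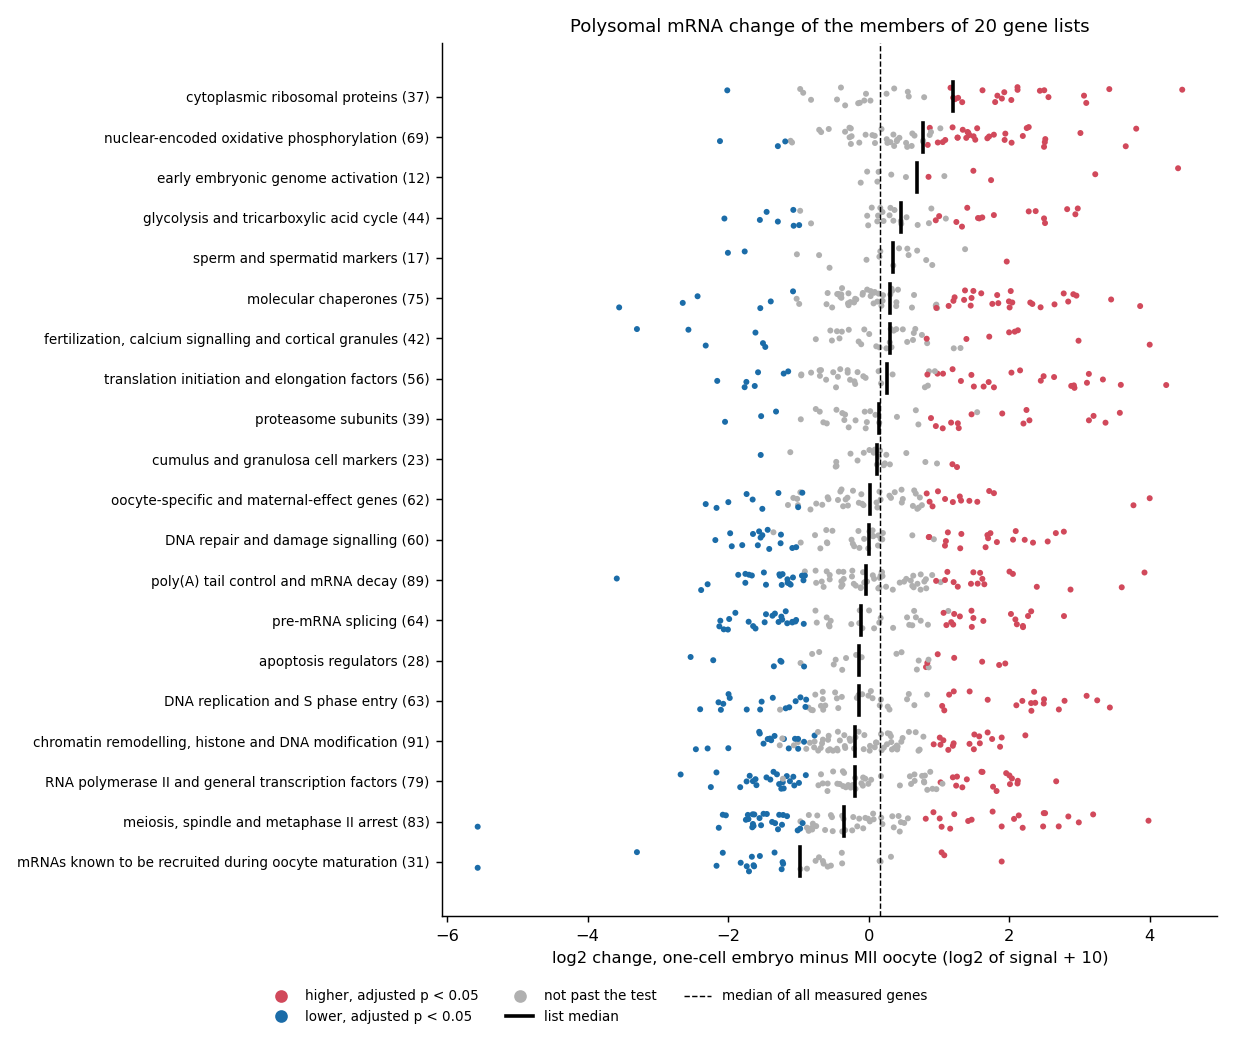
Log2 change in polysomal mRNA (one-cell embryo minus MII oocyte, x axis) of each measured member of 20 gene lists, with the number of members in parentheses, red and blue points for members that passed the test as higher or lower, a black bar at the list median and a dashed line at the median of all genes. Ribosomal protein and oxidative phosphorylation genes lie towards higher values (medians 1.20 and 0.77) and mRNAs recruited during maturation towards lower ones (-0.97), with the other lists between them.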

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

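The tests of the scaling, of one-cell array 1 as the source of the excess of higher probe sets, of cumulus cell markers and of probe sets that changed in opposite directions, and each setting that uses the hybridization controls, were chosen after the results were seen. Of 208 groups of 4 arrays checked for a single array far from the others on the log2 scale, 8 stood out. That is a smaller share than the 1 in 20 or so that chance gives for independent groups. Most of the groups come from named genes, many of them picked for changes without overlap, and all share the same 8 arrays. The rate is therefore not an exact reference, and whether chance alone produced the 8 is not decided. Mos was brighter on one-cell array 4 (437.1) than on the other one-cell arrays (251.3 to 259). One-cell array 1 stood apart for Gins4 (435.1 against 950.5 to 1102), Psma6 (6083 against 1749 to 2149) and Zp3 (1018 against 1769 to 1873). Akap4 was lowest on one-cell array 4 (6.1 against 22.4 to 25.9), Pkm on MII array 3 (39.6 against 118.1 to 145.6) and Hsph1 on MII array 2 (41.8 against 74.8 to 78.2). The poly(A) spike-in controls were brightest on one-cell array 2 (1539 against 228.9 to 262.7). Outside the mRNA measurements, the 18S 3′ probe set was 11.27-fold brighter in one-cell embryos. The middle probe set was 2.345-fold (exact p = 0.114) and the 5′ probe set 1.555-fold brighter (exact p = 0.0857), so the 3 differ widely.

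The real groups called more probe sets than any other split of the 8 arrays into 4 and 4. For them 7493 passed, and only 1 of the 35 splits, the real one, called that many, the smallest share possible. Limma called 0 in each of the others, where unadjusted p under 0.05 gave up to 3092 against 9445 for the real groups. Each other split mixes both kinds of array, which widens the spread within its groups, so few calls could arise there. The splits do not separate embryo stage from α-amanitin or from differences in array quality. More probe sets rose than fell (60.2%, and 52.36% with only probe sets above the 75th percentile). One-cell array 1 alone does not account for that excess, since 59.34% remained higher without it. The excess may come from scaling to a common mean on arrays of unequal brightness: under quantile normalization 48.56% were higher. Scaling and a true excess of rises cannot be told apart, because quantile normalization pushes the split towards balance by its construction, while 60.6% were higher without the 2 arrays with the brightest controls.

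Ribosomal protein genes were higher in one-cell embryos by a median of 1.04 relative to all genes. Uneven brightness of the hybridization controls and one-cell array 1 alone are argued against as the source. The relative median was 0.8547 with the control signal as a covariate (limma camera, adjusted p = 0.000957) and 0.9704 without one-cell array 1 (camera adjusted p = 0.000528). These 2 checks overlap, because that array has by far the brightest controls, and neither covers differences in amplification. Over all settings the relative median was lowest without one-cell array 2 (0.7449, camera adjusted p = 0.0114). As a set, the 23 measured cumulus and granulosa markers were not raised, with a relative median of -0.04429, 2 higher and 1 lower. The brightest of them, Col4a1 and Nr5a2, went from 404.4 to 273.2 and from 319.4 to 398.9. The marker median lay below that of the ribosomal proteins by 1.09 (permutation p = 0.0097 over 10000 shuffles of members). That test does not exclude RNA from these cells, since any list that is not shifted would give a similar gap. The shuffles also take genes as independent. None of the 40 genes of the marker list is in another list, and how many of them the egg itself expresses was not determined. Renewed loading of ribosomal protein mRNAs after fertilization is a hypothesis that stays open beside α-amanitin, RNA from other cells and differences in amplification. The camera call of the ribosomal list was also lost with an estimated correlation (adjusted p = 0.578 with all arrays, 0.498 without one-cell array 1).

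Of 4787 genes with at least 2 kept probe sets, 247 had probe sets that changed in opposite directions, and 1049 had 2 or more that changed the same way. Of the 23336 kept probe sets, 4511 were higher and 2982 lower, so unrelated probe sets would also often oppose each other. How many genes that would give was not computed, so the 247 are not shown to be an excess. For Dnmt3a, a de novo DNA methyltransferase, 1 probe set rose by 3.76 and another changed by -2.27, and for Dcp2 the values were 2.92 and -1.66. Probe sets marked as shared between transcripts are argued against as the main source, since 21.05% of the opposite genes held one (95% interval 16.1% to 26.7%), and so is dim signal, since 63.2% of opposite and 60.5% of other genes kept their calls among probe sets above the array median on all 8 arrays (ratio 1.043, 95% interval 0.937 to 1.16). Cross-hybridization in general cannot be told apart from a true difference: the ratio of 0.4175 to the share among other genes (50.4%) decides nothing, because pairs with a marked probe set agreed more in any case (correlation of changes 0.678 against 0.293 without one), and probe sequences were not used. Polysome loading that differs between mRNA forms with different 3′ ends is a candidate explanation that was not tested.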

How the results depend on the processing

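The covariate of the hybridization controls, the comparisons without 2 arrays or with quantile normalization and without one-cell array 1, and the estimated correlation without that array were chosen after the data were seen. The count of changed probe sets stayed within 5041 to 8597 over 22 alternatives. After quantile normalization 5889 of the 7493 were shared, the share higher was 48.56% (49.29% also without one-cell array 1), and median centring left 1571 genes higher. An adjusted p under 0.01 left 1108 genes lower, a stricter threshold by construction. The median change of all probe sets turned negative with quantile normalization (-0.12, and -0.13 without one-cell array 1), centring (-0.15), the 75th percentile filter (-0.0050), the covariate (-0.090) and without the 2 arrays (-0.023). Instead of 3 lists, 7 were shifted with quantile normalization or array weights and 8 with the covariate, without the 2 arrays, or with quantile normalization and without one-cell array 1. Leaving out single arrays gave 3 to 7, with 7 only without one-cell array 1. An estimated correlation gave 0, with or without that array (1 list at an unadjusted p under 0.05, 8 by fry). Dcp2 reversed to 0.63 when its probe sets were averaged, since they oppose each other. The other causes were not tested. Named genes gave 1877 values on the same side of the test over all alternatives and 46 no longer past it. Most of them were picked from these same arrays for large changes or small p, so this does not measure how stable other calls are. In the panel named in advance, Zar1 lost its call in 12 of 21 alternatives, Dnmt1 and Cdc6 in 8 each and Nlrp5 and Pou5f1 in 1 each. Mos, Plat, Gdf9 and H1f8 kept theirs in all 21. With the replicate number as a block, 7209 probe sets passed. Same-numbered arrays correlated at -0.16, -0.11, 0.14 and 0.04, and 2 of 4 were each other's best match, so the numbers were not used to pair them. Low MII signal limits the fold of 5 of the 12 largest rises, and that of Faf1 as well.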

Other observations

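The gene families and the Slc genes described here, and their tests, were chosen after the data were seen. Families were formed by the stem of the gene symbol, and 141 with at least 10 measured genes were tested with limma's camera. Besides the ribosomal proteins of the Rpl stem (adjusted p = 0.0211, and 0.895 with an estimated correlation), 2 families were called. The Rps stem did not pass, with 11 of 22 higher and 3 lower (camera adjusted p = 0.564). It takes in genes outside the cytoplasmic ribosomal protein list, which held only 1 lower gene, so it does not stand for the small ribosomal subunit. The Mrps family of the mitochondrial small subunit did not pass either, with 12 of 28 higher and 1 lower (camera adjusted p = 0.542). The Mrpl genes, which encode proteins of the large subunit of the mitochondrial ribosome, lay at a median of 0.83 relative to all genes, with 23 of 46 higher and 4 lower in one-cell embryos (adjusted p = 0.0211, and 0.895 with an estimated correlation). Mrpl48 rose from 188 ± 31.7 to 3734 ± 1562 (SD, n = 4), a log2 change of 4.15 ± 0.33 (SE), Mrpl51 by 2.58 ± 0.31 and Mrpl17 by 3.14 ± 0.38, while Mrpl44 (-1.07 ± 0.27) fell. The mean MII signal of Mrpl17 (22.3 ± 11.9) lay below the median of each MII array (26.9 to 33.8), so its fold is poorly set, and the other kept probe sets of Mrpl17 (0.03 ± 0.38) and Mrpl51 (0.89 ± 0.41) did not pass the test. The family stayed higher after quantile normalization (adjusted p = 0.0231) and without one-cell array 1 (0.00845).

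The Klhl genes, many of which encode substrate adaptors of cullin ubiquitin ligases, went the other way, with 9 of 22 lower and 1 higher and a relative median of -0.79 (adjusted p = 0.0211, and 0.895 with an estimated correlation). Klhl15 fell from 440 ± 101 to 146 ± 20.9 (SD, n = 4), a log2 change of -1.51 ± 0.28 (SE), Klhl28 changed by -1.67 ± 0.32 and Klhl2 by -1.64 ± 0.33, and Klhl30 rose (1.21 ± 0.44) from a mean MII signal of 24.1, below those medians as well. Another probe set of Klhl15 (0.35 ± 0.43) and another of Klhl28 (-0.18 ± 0.33) did not pass. Klhl18 changed by -2.51 ± 0.43, but another of its probe sets rose by 2.17 ± 0.34. The family stayed lower after quantile normalization (adjusted p = 0.0231) and without one-cell array 1 (0.0383).

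Slc35b3 was among the 12 largest falls, which raised the hypothesis that mRNAs of membrane transporters fell in general. The other Slc genes did not bear this out: of 247, 35 rose and 39 fell, and their median relative to all genes was -0.1229 (limma camera, unadjusted p = 0.141). Among the 141 families, the 248 Slc genes with Slc35b3 gave a camera adjusted p of 0.672.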
